A study of Homo sapiens with 54 samples.

How the data were processed

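Whole-transcript expression was measured on 54 one-colour oligonucleotide arrays, each hybridised with 1 RNA sample of NCI-H460 cells. Per the labels' protocols, cells in medium without serum received nicotine at 5 uM, smoke extract at 5 uM nicotine equivalent, or neither, and 2 h later 6 Gy of radiation, 1 uM cisplatin or neither. They were harvested 2 h or 24 h after that step, all treatments running concurrently on multi-well plates. The plate of each culture was not given in the sources used here, so plate could not be tested as a batch. RNA was isolated on silicon carbide spin columns with DNase treatment and amplified into sense-strand cDNA, per the labels' protocols. The labels call the 3 samples of each group biological replicates. The 54 arrays fall into 18 groups of 3, taken from the sample titles.

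The deposited values are taken to be on a log2 scale, because they ran from 0.89 to 13.81 with array medians from 6.43 to 6.63. The base of the logarithm is inferred from that range and not stated, so every fold change rests on it. Per the submitters' processing notes, the authors used Affymetrix Power Tools 1.15.0. The summarization, background correction and normalization were not given in the sources used here. The values were used as deposited. No detection calls were used here, so a low value cannot be separated from background, and changes from or to such a level, as for IL1B, VTRNA1-1 and ZNF814, are at best lower bounds.

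The table held 33297 rows, each a transcript cluster. Gene symbols came from the platform annotation provided with the data, where 19460 clusters had 1 symbol, 1754 had several and 12083 had none. Entrez identifiers of 19429 clusters were found in the reference list of genes, and 0 symbols needed an update. A gene was represented by the cluster with the highest mean over all 54 arrays among its clusters with exactly 1 symbol. This gave 18417 genes, 769 of them with more than 1 cluster. Near-identical genes such as replication-dependent histones, metallothioneins and small nucleolar RNAs can share probes, so their individual values are uncertain. No coordinates are given, because no genome build was named for the table. There were 0 sample columns left unused.

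Differences were tested with limma 3.58.1 in R 4.3.3, with the data.table package, version 1.17.8, for reading files. One linear model with 18 group means was fitted to all 54 arrays, leaving 36 residual degrees of freedom, and variances were moderated by eBayes with an intensity trend. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with genes called at an adjusted p under 0.05. The 28 comparisons were radiation, cisplatin, smoke extract and nicotine against untreated cells at each time, smoke extract or nicotine added to each therapy, F tests of whether the effects of smoke extract and nicotine differed by therapy, radiation against cisplatin, smoke extract against nicotine, untreated cells over time, and each single effect of radiation, cisplatin and smoke extract at 24 h minus that at 2 h. The choice of groups, tests, lists, named genes and most alternative settings was made before the data were examined.

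Named genes followed a fixed rule. For a single or added agent they were the 10 rising and the 10 falling genes with the largest absolute log2 change among called genes whose 3 arrays in each group did not overlap. For the other comparisons they were the 5 with the largest change each way, or for F tests the 5 with the smallest p. Up to 4 called members with the largest absolute change were eligible from each list. Where no gene was called, the 3 genes with the smallest p were given as values. CDKN1A and MDM2 were always given for radiation and cisplatin, CYP1A1, HMOX1 and NQO1 for smoke extract, and CHRNA5 and CHRNA7 for nicotine.

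The 19 gene lists covered p53 targets, G2/M and mitosis, DNA replication and G1/S, replication-dependent histones, DNA repair, NRF2 targets, AHR targets, heat shock, metallothioneins and zinc export, ATF4 and the unfolded protein response, immediate early genes, NF-kB and cytokines, interferon response, cholesterol synthesis, hypoxia and glycolysis, nicotinic receptors, the BCL2 family, oxidative phosphorylation, and markers of leukocytes, fibroblasts and endothelium. They held 513 memberships, of which 467 had a cluster with exactly 1 symbol, and the others were not analysed here. Camera tested each list in 16 comparisons with a preset inter-gene correlation of 0.01, adjusted over all 304 pairs of list and comparison. It called 116 pairs, and 18 of these held with a correlation estimated from the residuals, all of which are given in the results. Of the other calls, some at 2 h or with nicotine are given only as counts or left out. Fry, which tests whether a list's genes move on balance 1 way and compares them with no other genes, was adjusted over the same 304 pairs. A count in parentheses after a list's count is that adjusted over the list alone. Some genes belong to several lists, such as NQO1 and PMAIP1.

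Correlations between the changes of 2 therapies were set beside 100 simulations of unchanged groups against the same untreated arrays. Replicate numbers were checked for pairing through the correlation, across genes, of deviations from group means. All pairs exceeded 0.1 in 2 of 16 comparisons, nicotine against untreated cells at 24 h and smoke extract added to radiation at 24 h, where the lowest were 0.115 and 0.325 and the pairing comes only from that correlation.

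Arrays of 1 group differed along a main axis that held 36% of the variance within groups. As a per-array measure of this spread, the mean log2 value of 505 genes was taken from families not expected in these cells (olfactory and taste receptors, keratin-associated and late cornified envelope proteins, beta-defensins, PRAME family, vomeronasal receptors). DEFB1 is among these genes although it was called lower with smoke extract. That mean served as a covariate in an alternative added after the data were seen. Its slope is estimated within groups, and the fit then adjusts group differences for it as well. Another added alternative left out 4 arrays lying over 0.15 from their group in it.

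The alternatives set beforehand were a restriction to genes above the median of mean expression, all rows of the table as features, only the compared groups in the fit, quantile normalization across arrays, eBayes without trend, the replicate number as a block, each array left out in turn, the mean effect over the 3 backgrounds of the other factor, disjoint controls for the correlations, and the estimated correlation for camera. Other splits of the arrays, at most 100 per comparison, were counted as well.

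The procedures were tested on simulated data with 18417 genes, 50 of them changed at each size. For radiation at 24 h, limma recovered 20% of genes changed by 0.3 on the log2 scale, 64% at 0.5, 94% at 1 and 100% at 2, with 7 false calls. Smoke extract at 2 h gave 24%, 62%, 98% and 100%, with 6 false calls. Smoke extract by therapy at 24 h gave 8%, 34%, 94% and 100%, with 6. The smoke extract effect at 24 h minus that at 2 h gave 10%, 30%, 90% and 100%, with 4. Data without change gave 0 calls. Of the lists only the p53 list, shifted by 0.4, was called. Whether these rates hold along the main axis of spread was not tested.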

Results

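Gene expression was measured in NCI-H460 cells, an established line from a human large cell carcinoma of the lung, that had been kept without serum and then exposed to nicotine, cigarette smoke extract, ionizing radiation, cisplatin or combinations of these. The 54 arrays formed 18 groups of 3 arrays. Each group joined 1 of 3 pretreatments (none, 5 uM nicotine, or smoke extract holding 5 uM nicotine) with 1 of 3 therapies (none, 6 Gy of radiation, or 1 uM cisplatin) and with harvest 2 h or 24 h after the therapy step. The pretreatment preceded that step by 2 h. Cisplatin is a platinum drug that crosslinks DNA, and radiation breaks DNA strands. Levels are log2 values as deposited, with errors of single levels as SD over 3 arrays and errors of changes as the SE of the limma fit. Pearson correlations between arrays of 1 group over all 33297 rows ranged from 0.979 to 0.996, and no pair of arrays was identical. The number of arrays limits the precision.

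The first question was what radiation alone did to the cells. At 2 h, targets of the p53 transcription factor rose. CDKN1A, which encodes the cell cycle inhibitor p21, went from 8.42 ± 0.03 to 9.68 ± 0.16 (SD, n = 3 each), a 2.39-fold increase. The stress gene GADD45A rose 2.22-fold, the kinase gene PLK3 rose 2.10-fold, TP53INP1 rose 2.10-fold, SESN1 rose 2.01-fold, the death receptor gene FAS rose 1.84-fold, and MDM2, whose product degrades p53, rose 1.51-fold. Of 44 measured p53 targets, 16 rose and 0 fell over all genes tested, and 33 rose when adjusted over the list alone. Genes of cell division moved the other way. WEE1, an inhibitor kinase of mitotic entry, fell by 1.07 ± 0.16 on the log2 scale, the cyclin gene CCNF fell by 0.96 ± 0.09, ASPM fell by 0.47 and PLK1 fell by 0.31. Among 40 genes of G2/M and mitosis, 4 fell and 0 rose, with 17 falling when adjusted over the list alone. The histone genes H2AC15 and H1-3 fell by 0.91 and 0.83, although near-identical histone genes can share probes and are uncertain individually. In all, limma called 56 of 18417 genes, 25 higher and 31 lower, and 21 of them changed over 1.5-fold. The camera test placed the p53 targets above other genes (adjusted p = 3.33e-77, and adjusted p = 2.58e-06 with an estimated correlation) and the mitosis genes below them (adjusted p = 6.47e-27, and adjusted p = 0.0339 with an estimated correlation). Single arrays ended the calls of 4 of these genes. H1-3 (adjusted p from 0.07 to 0.162) and PLK1 (0.0866 to 0.3) lost theirs on leaving out any array but radiation 2 h replicate 3, H2AC15 (0.108 to 0.416) on leaving out any but radiation 2 h replicate 2, and ASPM (0.066 to 0.0825) without untreated or radiation 2 h replicates 1 or 2. PLK1 and H2AC15 were also not called over all rows of the value table (adjusted p = 0.0543 and 0.0876), nor PLK1 with eBayes without trend (adjusted p = 0.0596). The count was 148 without radiation 2 h replicate 3, 27 without radiation 2 h replicate 1, 28 without radiation 2 h replicate 2, and 27, 30 and 37 without untreated 2 h replicates 1, 2 and 3. It was 249 for the mean radiation effect over the 3 pretreatments and 222 with only the compared groups in the fit (71 of them higher). It was 92 without the 4 arrays far from their group in silent-family mean. With that mean as a covariate, added after the data were seen, it was 135, with 39 higher and 96 lower.

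By 24 h the response to radiation had widened to 3875 called genes, 1850 higher and 2025 lower, of which 818 changed over 1.5-fold. The larger share was higher under both other scalings, with 2476 higher and 1941 lower under quantile normalization and 2593 and 2219 with the silent-family covariate. The p53 targets stayed high, with 35 of 44 called higher and 0 lower (38 when adjusted over the list alone) and a median log2 change of 0.61. TP53INP1 rose 3.80-fold, SESN1 2.77-fold, GADD45A 2.66-fold, MDM2 1.86-fold and CDKN1A 1.70-fold. Among other genes, SULF2, a sulfatase of heparan sulfate, went from 6.97 ± 0.13 to 8.78 ± 0.10, and the smooth muscle actin gene ACTA2 rose 3.04-fold. Proliferation genes fell broadly. Of 39 replication and G1/S genes, 37 fell and 0 rose (37), with a median of -0.74, including CCNE2 (fell by 1.91 ± 0.19) and the ribonucleotide reductase gene RRM2 (fell by 1.64 ± 0.11). Of 40 mitosis genes, 34 fell and 0 rose (36), among them AURKB, which fell by 1.54, and CCNA2, which fell by 1.14. Replication-dependent histone genes fell in 13 of 18 cases (14), with a median of -1.09. H3C12 fell by 3.02 ± 0.13 and H2BC14 fell by 2.97 ± 0.10. Genes of cholesterol synthesis fell in 15 of 17 cases (15), such as EBP, which fell by 1.05, and LSS, which fell by 0.68. Camera called these 5 lists (adjusted p = 3.79e-33 for p53 targets, 3.02e-30 for mitosis, 1.56e-45 for replication, 2.78e-19 for histones and 2.68e-15 for cholesterol synthesis), and each call held with an estimated correlation, where adjusted p was 0.00237 for p53 targets, 0.023 for mitosis, 0.00105 for replication, 0.00283 for histones and 0.00326 for cholesterol synthesis. DNA repair genes fell in 16 of 41 cases and rose in 1 (18 and 1), oxidative phosphorylation genes fell in 15 of 30 and rose in 1 (16 and 2), and heat shock genes fell in 11 of 20 and rose in 1 (12 and 1). Those 3 list calls were lost with an estimated correlation (adjusted p = 0.505, adjusted p = 0.348 and adjusted p = 0.224). Of 91 small nucleolar and Cajal body RNAs with mean levels above the median gene, a class chosen after the data were seen and not tested as a list, 62 were called lower and 1 higher (median -0.64), with SNORA23 falling by 2.14 ± 0.24. The vault RNA VTRNA1-1 fell by 2.70 ± 0.39. The mean effect over the 3 pretreatments gave 5992 called genes.

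Cisplatin was compared with no treatment in the same way. After 2 h, limma called 1 gene, the phosphatase gene DUSP1, which fell by 0.75 ± 0.11 (adjusted p = 0.000178), from 10.24 ± 0.04 to 9.48 ± 0.17. CDKN1A and MDM2 had log2 changes of -0.16 ± 0.16 and -0.04 ± 0.11, short of the threshold. After 24 h, 700 genes were called, 396 higher and 304 lower. The p53 targets rose in 16 of 44 cases and fell in 0 (19 rose when adjusted over the list alone), with SESN1 up 1.55-fold, TP53INP1 up 1.51-fold and TIGAR up by 0.59 on the log2 scale. CDKN1A (0.26 ± 0.16, adjusted p = 0.358) and MDM2 (0.28 ± 0.11, adjusted p = 0.134) did not pass the limma test. The call of TIGAR ended on leaving out any 1 of the 6 arrays (adjusted p from 0.0713 to 0.146), over all rows (adjusted p = 0.0554) and for the mean over the 3 pretreatments (0.22, adjusted p = 0.202). That of TP53INP1 ended without untreated 24 h replicate 2 (adjusted p = 0.0646) or cisplatin 24 h replicate 3 (adjusted p = 0.0784), while without cisplatin 24 h replicate 2 MDM2 passed (0.43, adjusted p = 0.0365). PDCD4, a translation inhibitor, rose 1.78-fold. The chemokine gene CXCL8 fell by 1.23 ± 0.13 and DUSP1 fell by 0.70 ± 0.11. Immediate early genes, which respond first to growth signals, fell in 9 of 26 cases and rose in 0 (10). Replication-dependent histones fell in 3 of 18 cases (4) and metallothioneins with zinc export genes in 2 of 9 (4 fell and 1 rose). The camera calls of these 4 lists were lost with an estimated correlation (adjusted p = 0.131, 0.243, 0.333 and 0.264 in that order). The same 3 cisplatin arrays enter the p53 falls below with smoke extract or nicotine added. Camera called 3 more lists. Mitosis genes were called in 3 of 40 cases higher and 1 lower (7 and 3 when adjusted over the list alone, median 0.15, adjusted p = 0.000304), oxidative phosphorylation genes in 4 of 30 lower (median -0.11), and of 15 nicotinic receptors 0 were called (median -0.17, adjusted p = 0.178 by fry), and with an estimated correlation adjusted p was 0.624, 0.555 and 0.622. The silent-family mean was 0.079 lower after cisplatin, and with it as a covariate the mitosis median was 0.105 (adjusted p = 0.0194). The mitosis call also ended among genes above the median of mean expression (adjusted p = 0.0615), and that of receptors with quantile normalization (-0.11, adjusted p = 0.0823), with the covariate (-0.105, adjusted p = 0.177) and among the genes above the median, where it turned (0.03, adjusted p = 0.955). Of the 91 small nucleolar and Cajal body RNAs, 45 were called lower and 1 higher (median -0.48), with SNORA23 falling by 2.05 ± 0.24 and SNORA3A by 1.89 ± 0.22. The count at 24 h was 241 with only the compared groups, 1248 with the covariate, 1489 without the far arrays and 1072 over all rows. It was 330, 225 and 262 without untreated 24 h replicates 1, 2 and 3. Without cisplatin 24 h replicates 2 and 3 it was 250 and 450. The mean over the 3 pretreatments gave 927, with 370 of the 700. With the covariate 535 were higher and 713 lower, against 396 and 304.

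Radiation and cisplatin differed in 52 genes at 2 h and 2403 at 24 h. At 2 h, CDKN1A was 2.67-fold and SESN1 2.53-fold higher after radiation, while CCNF was 1.66-fold lower. At 24 h, SULF2 was 2.77-fold higher after radiation, H2BC14 5.87-fold lower and CCNE2 3.76-fold lower. At 2 h the count was 33, 25 and 130 without radiation 2 h replicates 1, 2 and 3, and 30 and 33 without cisplatin 2 h replicates 1 and 2. At 24 h it was 1524 and 1432 without radiation 24 h replicates 1 and 2, 1404 without cisplatin 24 h replicate 3, and 816 with only the compared groups, 215 of them higher. At 2 h, 43 genes were higher after radiation and 9 lower, against 57 and 43 with the silent-family covariate. At 24 h, 947 were higher and 1456 lower, against 1351 and 1297 with quantile normalization and 1183 and 1052 with the covariate. The log2 changes of both against their shared untreated arrays correlated across genes at r = 0.343 at 2 h and 0.533 at 24 h. Genes are not independent replicates, and unchanged groups simulated against shared controls gave r = 0.50 at each time. The covariance was 0.0281 against a simulated 0.00748 at 24 h (difference 0.0206) and 0.00385 against 0.00745 at 2 h (-0.0036). The correlation was 0.213 without cisplatin 2 h replicate 2 and 0.335 without cisplatin 24 h replicate 2. With disjoint controls, where cisplatin + nicotine against nicotine replaced the cisplatin effect, it was 0.114 at 2 h and 0.56 at 24 h. Nicotine thus enters these values. At 24 h, 293 genes were higher after both therapies where independent lists would share 39.8, and 238 were lower where they would share 33.4. Part of that excess may come from the shared controls.

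Smoke extract gave the sharpest early response, although it was added 2 h before the therapy step and so had longer to act than radiation or cisplatin. At 2 h after the therapy step, targets of the aryl hydrocarbon receptor (AHR), a sensor of combustion products, rose in 6 of 10 cases and fell in 0 (6 when adjusted over the list alone). CYP1A1, which encodes a detoxifying P450 enzyme, went from 5.24 ± 0.10 to 8.61 ± 0.16, a 10.3-fold increase. Its values on the 36 arrays without smoke extract, 4.84 to 5.87, lay near the silent-family means, so its folds here and below are at best lower bounds. TIPARP rose 6.78-fold, STC2 rose 4.18-fold and CYP1B1 rose 3.72-fold. Outside that list, the cytokine gene IL1A rose 3.56-fold, the growth factor gene EPGN 3.54-fold, NDRG1 3.15-fold, PPP1R15A 1.63-fold and CDKN1A 1.57-fold. IL6 fell by 1.43 ± 0.21, DUSP1 by 1.15, DUSP6 by 1.08, the Wnt antagonist gene DKK1 by 1.06, NR4A1 by 1.04 and PTGS2 by 0.88 on the log2 scale. Replication and G1/S genes fell in 5 of 39 cases (13), including E2F8, which fell by 0.66. Among 28 targets of NRF2, the regulator of antioxidant genes, 3 rose and 1 fell (3 and 1). HMOX1 rose 1.30-fold, and NQO1 had a log2 change of 0.07 ± 0.04 (adjusted p = 0.594). The call of HMOX1 ended on leaving out any array but smoke extract 2 h replicate 2, with adjusted p from 0.0575 to 0.0884. Limma called 695 genes, 320 higher and 375 lower. Camera called the AHR targets (adjusted p = 6.05e-37, and adjusted p = 1.92e-12 with an estimated correlation), whereas its calls of replication and NRF2 lists were lost with an estimated correlation (adjusted p = 0.327 and adjusted p = 0.511). The count was 1710 for the mean effect over the 3 therapies, 1278 with only the compared groups and 450 without smoke extract 2 h replicate 2.

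**Figure D1:**
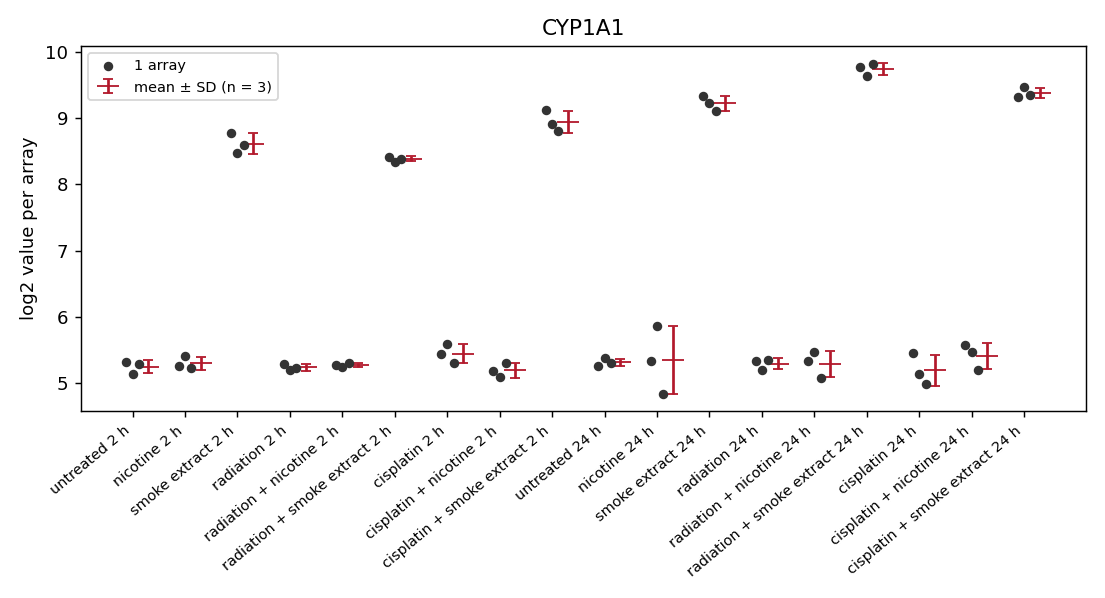
The log2 value of CYP1A1 (vertical axis) on each of the 54 arrays, by group (horizontal axis), with 1 point per array and the mean ± SD of 3 arrays beside them. Every group that received smoke extract lies above every group that did not, with 8.61 after smoke extract against 5.24 in untreated cells at 2 h.

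At 24 h, smoke extract changed 2959 genes, 1597 upward and 1362 downward. The collagenase gene MMP1 went from 6.26 ± 0.16 to 10.36 ± 0.17, a 17.2-fold increase. CYP1A1 was 15.1-fold, SCUBE1 7.46-fold, IL1A 6.29-fold, TIPARP 6.06-fold, CYP1B1 3.60-fold, STC2 3.30-fold and IL1B 2.39-fold higher. AHR targets rose in 6 of 10 cases (6 when adjusted over the list alone), and genes of NF-kB and cytokines rose in 7 of 22 and fell in 2 (8 and 3). NRF2 targets rose in 11 of 28 cases and fell in 2 (11 and 2), by small amounts such as 1.35-fold for HMOX1, 1.35-fold for the glutathione synthesis gene GCLM and 1.11-fold for NQO1. NQO1 did not pass without untreated 24 h replicate 3 (adjusted p = 0.0585), without smoke extract 24 h replicate 2 (adjusted p = 0.0593) or with only the compared groups (adjusted p = 0.111). Targets of ATF4 and the unfolded protein response fell in 15 of 30 cases and rose in 0 (18 fell). These included the serine synthesis genes PHGDH, which fell by 1.03 ± 0.13, and PSAT1, which fell by 0.80 ± 0.10, and the cysteine synthesis gene CTH, which fell by 0.93 ± 0.15. Mitosis genes fell in 15 of 40 cases and rose in 1 (17 and 1), including AURKA, which fell by 0.91, and CDK1, which fell by 0.89. Replication genes fell in 8 of 39 cases and rose in 1 (10 and 2) and heat shock genes fell in 4 of 20 and rose in 1 (5 and 1). Histones fell in 8 of 18 cases (12) and oxidative phosphorylation genes in 16 of 30 with 1 rising (17 and 3). The defensin gene DEFB1 fell by 2.08 ± 0.25, DKK1 by 1.63 ± 0.14 and the small nucleolar RNA SNORA20 by 1.74 ± 0.32 on the log2 scale. The AHR and ATF4 lists were called by camera with a preset correlation and with an estimated one (adjusted p = 4.13e-08 and adjusted p = 0.0247). With an estimated correlation, adjusted p was 0.463 for mitosis, 0.256 for histones, 0.505 for NRF2 targets, 0.497 for NF-kB genes, 0.634 for replication, 0.583 for heat shock and 0.496 for oxidative phosphorylation, so those calls were lost. The NRF2 and NF-kB calls also ended among genes above the median expression (medians 0.06 and 0.31 against 0.07 and 0.18, adjusted p = 0.1 and adjusted p = 0.0615), and the heat shock call there, with quantile normalization and with the covariate (adjusted p = 0.265, 0.113 and 0.0742). The mean effect over the 3 therapies gave 5096 called genes, and leaving out smoke extract 24 h replicate 3 gave 1903.

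Nicotine alone, at the amount held by the smoke extract, gave few or no calls. At 2 h limma called 0 genes, with 109 at an unadjusted p under 0.05. The smallest p-values belonged to NLE1 (log2 change -0.42 ± 0.10), CYSLTR1 (-0.42 ± 0.13) and ZNF382 (-0.38 ± 0.12), each with adjusted p = 1. At 24 h it called 1 gene, the RNA methyltransferase gene FTSJ1, which fell by 0.40 ± 0.07 (adjusted p = 0.0142), with 1074 genes at an unadjusted p under 0.05. The nicotinic receptor genes CHRNA5 and CHRNA7 had log2 changes of 0.05 ± 0.08 and -0.05 ± 0.15 at 2 h and of -0.02 ± 0.08 and -0.17 ± 0.15 at 24 h. Of 15 measured nicotinic receptor genes, 0 were called at 24 h. Camera called 5 lists at 24 h with 0 members called in them. Genes of replication (median -0.08, adjusted p = 0.000589), oxidative phosphorylation (-0.11, 0.00116), DNA repair (-0.08, 0.0151) and mitosis (-0.10, 0.0311) lay lower and markers of leukocytes, fibroblasts and endothelium higher (0.05, 0.0223). With an estimated correlation these calls were lost (adjusted p = 0.606, 0.511, 0.776, 0.817 and 0.537), as they were among genes above the median expression (adjusted p = 0.0794, 0.0905, 0.485, 0.608 and 0.277). Without the far arrays, which include nicotine 24 h replicate 2, 0 of the 5 were called, and the medians were -0.03, -0.105, 0.05, -0.02 and -0.0006. At 2 h camera called 2 lists, heat shock and oxidative phosphorylation genes, with 0 members called and adjusted p = 0.572 and 0.521 with an estimated correlation. With only the compared groups, or without untreated 24 h replicate 2, untreated 24 h replicate 3 or nicotine 24 h replicate 2, limma called 0 genes (adjusted p of FTSJ1 was 1, 0.0725, 0.652 and 0.356 in that order), and without nicotine 24 h replicate 1 it called 4. The mean nicotine effect over the 3 therapies called 959 genes at 24 h, 144 of them higher, a mean that includes the cisplatin arrays described further on. Direct comparison of smoke extract with nicotine called 624 genes at 2 h and 2349 at 24 h. CYP1A1 was 9.95-fold higher and IL6 2.71-fold lower with smoke extract at 2 h, and MMP1 was 19.7-fold higher and DEFB1 3.12-fold lower at 24 h. The count at 24 h was 1353, 915 and 3866 without nicotine 24 h replicates 1, 2 and 3, 1435 and 1530 without smoke extract 24 h replicates 1 and 3, 1119 without the far arrays and 504 with only the compared groups.

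**Figure D2:**
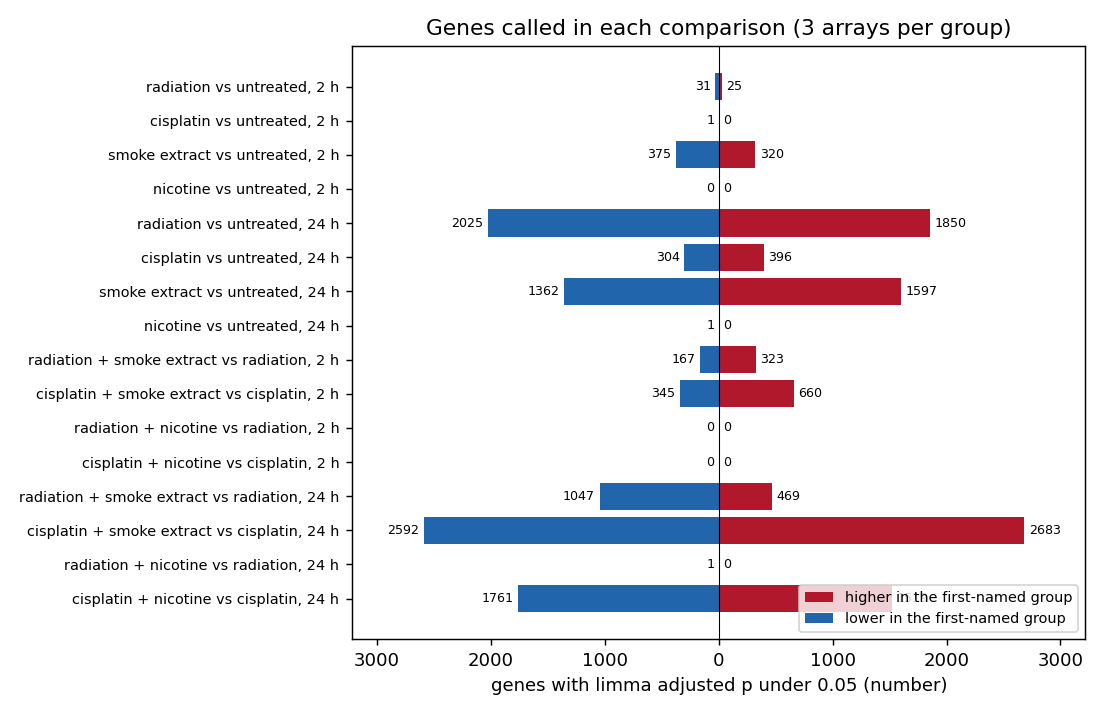
Number of genes with a limma adjusted p under 0.05 (horizontal axis) in 16 comparisons (vertical axis), with genes higher in the first-named group to the right and lower ones to the left. Smoke extract called genes on each therapy background at both times, from 490 to 5275 in all, while nicotine called at most 1 gene in 5 of its 6 comparisons and 3280 in cisplatin-treated cells at 24 h.

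The combinations asked whether smoke extract acted in the same way in cells given radiation or cisplatin. At 2 h, 490 genes changed when smoke extract was added to radiation, 323 higher and 167 lower. CYP1A1 rose 8.86-fold, TIPARP 7.25-fold and CYP1B1 3.98-fold, while DKK1 fell by 1.32 ± 0.14 and IL6 by 1.30 ± 0.21. HMOX1 (0.12 ± 0.10, adjusted p = 0.903) and NQO1 (0.02 ± 0.04, adjusted p = 0.982) did not pass. The count was 762 with only the compared groups, 426 of them higher. AHR targets rose in 6 of 10 cases (6 when adjusted over the list alone). Among p53 targets 5 of 44 fell and 0 rose (9 fell), such as TP53INP1, which fell by 0.61, and PPM1D, which fell by 0.43, and replication genes fell in 4 of 39 cases (10). Without radiation + smoke extract 2 h replicate 1 the calls of TP53INP1 (-0.50, adjusted p = 0.0864) and PPM1D (-0.36, adjusted p = 0.101) ended, and without radiation 2 h replicate 2 that of PPM1D (-0.39, adjusted p = 0.071). Adding smoke extract to cisplatin changed 1005 genes at 2 h, 660 higher and 345 lower. CYP1A1 rose 11.3-fold, TIPARP 6.44-fold, GDF15 1.95-fold and HMOX1 1.67-fold, and IL6 fell by 1.29 ± 0.21. NQO1 had a log2 change of 0.11 ± 0.04 (adjusted p = 0.132, and 0.0438 without the far arrays). The call of GDF15 ended without replicate 1 or 2 of either group, with adjusted p from 0.0572 to 0.11. The count was 465 with only the compared groups, 300 of them higher, and 1237 without the far arrays, 1030 of them higher. AHR targets rose in 7 of 10 cases (8) and replication genes fell in 4 of 39 (6). The AHR calls held with an estimated correlation in both settings (adjusted p = 1.56e-12 with radiation and adjusted p = 5.43e-11 with cisplatin). The calls of p53 targets with radiation and of replication genes with radiation and with cisplatin were lost (adjusted p = 0.463, adjusted p = 0.243 and adjusted p = 0.325), the last also without the far arrays (median -0.01 against -0.13, adjusted p = 0.136). The 3 backgrounds share no arrays, and 234 genes were higher and 91 lower with smoke extract in all 3. With smoke extract alone and with smoke extract added to radiation, 248 genes were called higher in both where independent lists would share 5.61, and 121 lower where they would share 3.40. Limma's test of whether the smoke extract effect differed by therapy at 2 h called 0 genes, with 1167 at an unadjusted p under 0.05. Its smallest p-values were those of OSBPL10, MALAT1 and TRIP6 (adjusted p = 0.279, 0.386 and 0.386), whose log2 interactions with radiation were -0.14, 0.32 and -0.02. OSBPL10 passed with the silent-family covariate (adjusted p = 0.0102) and without the far arrays (adjusted p = 0.0157). Without radiation 2 h replicate 3 the test called 5 genes, MALAT1 among them (adjusted p = 0.00268), and without cisplatin 2 h replicate 2 it called 1.

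At 24 h the addition of smoke extract to radiation changed 1516 genes, 469 higher and 1047 lower. MMP1 rose 24.7-fold, CYP1A1 21.9-fold, IL1A 8.28-fold and IL1B 3.85-fold. AHR targets rose in 6 of 10 cases and fell in 1 (6 and 2 when adjusted over the list alone). Of 40 mitosis genes, 38 fell and 0 rose (38), with a median log2 change of -1.06. KIF20A, a mitotic kinesin, fell by 1.69 ± 0.08, CDK1 by 1.52 ± 0.18 and TTK by 1.40 ± 0.16. Replication genes fell in 33 of 39 cases (34), led by CDC6, which fell by 1.32, and DNA repair genes in 12 of 41 (13), led by XRCC2, which fell by 1.02. ATF4 targets fell in 15 of 30 cases (18), including PHGDH, which fell by 0.81. NRF2 targets rose in 5 of 28 cases (9), whereas HMOX1 (0.30 ± 0.10, adjusted p = 0.057) and NQO1 (0.04 ± 0.04, adjusted p = 0.785) did not pass. HMOX1 passed without radiation 24 h replicate 1 (0.36, adjusted p = 0.0358), with quantile normalization (adjusted p = 0.0287), with the covariate (adjusted p = 0.0418), without the far arrays (adjusted p = 0.0426) and among genes above the median expression (adjusted p = 0.0357). With an estimated correlation, adjusted p was 1.66e-05 for mitosis, 0.00105 for replication, 0.0271 for ATF4 and 6.15e-09 for AHR targets, and the calls of NRF2 targets (adjusted p = 0.0998) and DNA repair genes (adjusted p = 0.494) were lost. With only the compared groups the count was 651.

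The test of whether smoke extract acted differently by therapy called 399 genes at 24 h. Of these, 281 had a radiation interaction below 0, which means a lower level than the separate effects add up to. The 5 smallest p-values were all those of mitotic genes. The log2 interaction with radiation was -1.45 for KIF20A, -1.13 for TOP2A, -1.10 for TPX2, -1.02 for PLK1 and -1.16 for NCAPG, while that with cisplatin was -0.29, -0.35, -0.16, -0.15 and -0.31. Among 40 mitosis genes, 23 were called, with a median of -0.81 for radiation and -0.22 for cisplatin. Among 39 replication genes, 18 were called, with medians of -0.48 and -0.18. The mean level of the 40 mitosis genes was 9.15 ± 0.06 in untreated cells, 8.91 ± 0.05 with smoke extract, 8.57 ± 0.11 with radiation and 7.61 ± 0.14 with radiation and smoke extract. The count of 399 became 254 and 198 without untreated 24 h replicates 1 and 2, 230 and 236 without smoke extract 24 h replicates 1 and 3, and 235, 207 and 1635 without radiation 24 h replicates 1, 2 and 3. It became 655 without radiation + smoke extract 24 h replicate 2 and 1335 without cisplatin 24 h replicate 2, and it was 635 with quantile normalization, 672 with the silent-family covariate, 1096 without the far arrays and 115 with only the compared groups.

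**Figure D3:**
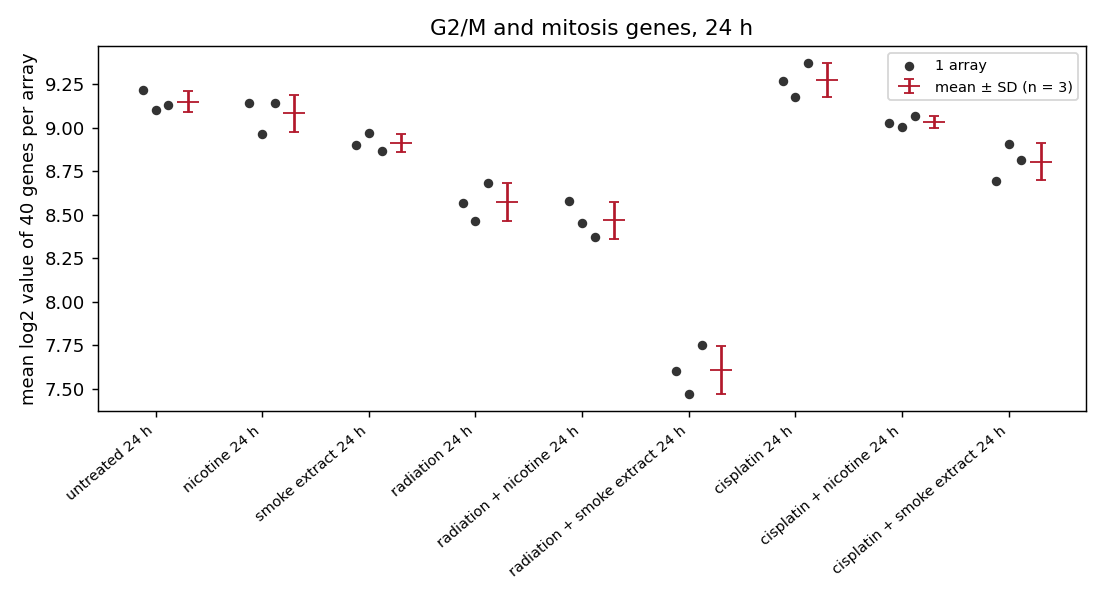
Mean log2 value of 40 G2/M and mitosis genes (vertical axis) on each array of the 9 groups harvested at 24 h (horizontal axis), with 1 point per array and the mean ± SD of 3 arrays beside them. The arrays of radiation with smoke extract lie lowest, from 7.47 to 7.75.

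Adding smoke extract to cisplatin for 24 h gave 5275 called genes, 2683 higher and 2592 lower. MMP1 rose 19.1-fold, CYP1A1 18.2-fold, SCUBE1 6.69-fold and HMOX1 1.34-fold, and NQO1 had a log2 change of 0.10 ± 0.04 (adjusted p = 0.0574). NQO1 passed without cisplatin 24 h replicate 2 (0.12, adjusted p = 0.033), without the far arrays (adjusted p = 0.0481) and among genes above the median expression (adjusted p = 0.0337). Mitosis genes fell in 34 of 40 cases and rose in 1 (36 and 1 when adjusted over the list alone), with CENPE falling by 1.05 and AURKA by 0.95. ATF4 targets fell in 16 of 30 cases and rose in 3 (20 and 3), with CTH falling by 1.07, and p53 targets fell in 14 of 44 (15 fell and 1 rose), with TIGAR falling by 0.87 and MDM2 by 0.50. AHR targets rose in 5 of 10 cases (6 rose and 1 fell). With an estimated correlation the AHR (adjusted p = 2.58e-06) and ATF4 (adjusted p = 0.0467) calls held, and those of mitosis genes (adjusted p = 0.0886) and p53 targets (adjusted p = 0.497) were lost. The p53 call also ended with the covariate, where the median went from -0.23 to -0.04 (adjusted p = 0.227), and among genes above the median expression, where it was -0.235 (adjusted p = 0.108). DNA repair genes fell in 11 of 41 cases (11), heat shock genes in 8 of 20 (8), histones in 5 of 18 (5) and oxidative phosphorylation genes in 5 of 30 (2), and those camera calls were lost with an estimated correlation (adjusted p = 0.511, 0.444, 0.61 and 0.726) and with the covariate, where the medians were -0.03, -0.07, -0.07 and 0.02, and among genes above the median expression (adjusted p from 0.0718 to 0.808). All but the DNA repair call ended with quantile normalization as well (adjusted p from 0.0541 to 0.56). The 505 genes of silent families, such as olfactory receptors, were on average 0.24 higher with smoke extract here, and 118 of them were called. Markers of leukocytes, fibroblasts and endothelium were higher in 3 of 17 cases and lower in 0 (1 and 0), with a median log2 change of 0.21. They had adjusted p = 0.0373 by fry and 0.115 by camera. With the silent-family mean as a covariate 1317 genes were called, 1109 of them among the 5275, and without cisplatin 24 h replicate 3 the count was 1450. It was 2501 and 3424 without cisplatin + smoke extract 24 h replicates 1 and 3, 1957 with only the compared groups, 674 of them higher, and 3024 among the genes above the median expression, 793 of them higher, where 2683 of the 5275 were. Across the 3 backgrounds at 24 h, 272 genes were higher and 357 lower with smoke extract in all 3.

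Nicotine added to radiation or cisplatin was tested for the same question. At 2 h limma called 0 genes with radiation, with 286 at an unadjusted p under 0.05, and 0 with cisplatin, with 324. The smallest p-values were those of SNORD32B (-0.58 ± 0.16), SELENOW (-0.30 ± 0.08) and PAGE2B (0.72 ± 0.21) with radiation and of MRPL34 (0.32 ± 0.07), ODAD4 (0.36 ± 0.10) and PRECSIT (0.42 ± 0.13) with cisplatin, as log2 changes. When nicotine was added to radiation at 24 h 1 gene was called, H2BC21, which fell by 0.93 ± 0.15 (adjusted p = 0.0035), with 1035 genes at an unadjusted p under 0.05. That count was 34 without radiation + nicotine 24 h replicate 1, 11 without radiation 24 h replicate 3 and 0 without radiation 24 h replicate 2, radiation + nicotine 24 h replicate 2 or radiation + nicotine 24 h replicate 3, where adjusted p of H2BC21 was 0.0709, 0.559 and 0.0941. With only the compared groups 0 genes were called, and adjusted p of H2BC21 was 1. With the silent-family covariate 2 genes were called. The log2 changes of CHRNA5 and CHRNA7 with nicotine at 2 h were -0.0023 ± 0.076 and -0.018 ± 0.15 with radiation and 0.022 ± 0.076 and 0.031 ± 0.15 with cisplatin. At 24 h they were -0.20 ± 0.08 and 0.03 ± 0.15 with radiation and -0.07 ± 0.08 and -0.11 ± 0.15 with cisplatin, and none of these passed. Camera called 3 lists with radiation and 8 with cisplatin at 2 h, with 0 members called in them, and 7 with radiation at 24 h, with 1 member called. None of these held with an estimated correlation, the lowest adjusted p being 0.359, 0.423 and 0.412.

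In cisplatin-treated cells at 24 h, nicotine came with 3280 called genes, 1519 higher and 1761 lower, of which 183 changed over 1.5-fold. Mitosis genes fell in 13 of 40 cases (21 when adjusted over the list alone), p53 targets in 9 of 44 (14 fell and 1 rose), with MDM2 falling by 0.53, and nicotinic receptor genes rose in 3 of 15 (8). These list calls were lost with an estimated correlation (adjusted p = 0.406, adjusted p = 0.484 and adjusted p = 0.496). ZNF814 fell by 1.38 ± 0.28, the proteasome gene PSMB5 fell by 0.92 ± 0.26, the small nucleolar RNA SNORA38B rose 2.02-fold, and the olfactory receptor gene OR4C16 rose 1.57-fold. Without cisplatin 24 h replicate 3 the calls of MDM2, ZNF814, PSMB5, SNORA38B and OR4C16 ended (adjusted p = 0.0654, 0.0615, 0.189, 0.0965 and 0.12), as they did with the silent-family covariate, where the log2 changes were -0.38, -0.88, -0.62, 0.94 and 0.33 (adjusted p = 0.0973, 0.0971, 0.31, 0.136 and 0.314) against -0.53, -1.38, -0.92, 1.01 and 0.65. Without cisplatin + nicotine 24 h replicate 1 those of PSMB5, SNORA38B and OR4C16 ended (adjusted p = 0.0515, 0.0664 and 0.0639), and that of PSMB5 without cisplatin 24 h replicate 1 (adjusted p = 0.067) or cisplatin + nicotine 24 h replicate 2 (adjusted p = 0.0544). The p53 and receptor list calls ended with the covariate, where the medians went from -0.19 to -0.04 and from 0.30 to 0.08 (adjusted p = 0.0794 and 0.146), and among genes above the median expression, where they were -0.19 and 0.08 (adjusted p = 0.0787 and 0.51). Genes of replication fell in 12 of 39 cases (16), DNA repair in 10 of 41 (12), NRF2 targets in 7 of 28 (8), hypoxia in 4 of 23 (8), heat shock in 3 of 20 (4) and interferon response in 4 of 23 with 2 rising (4 and 2), and these calls were lost with an estimated correlation too (adjusted p = 0.511, 0.494, 0.359, 0.348, 0.549 and 0.366). The covariate also ended those of replication (median -0.05, adjusted p = 0.0687), DNA repair (-0.01, adjusted p = 0.0638) and heat shock genes (-0.05, adjusted p = 0.41). Quantile normalization ended those of heat shock (adjusted p = 0.207) and hypoxia (adjusted p = 0.0541), and all but the DNA repair call ended among genes above the median expression (adjusted p from 0.0615 to 0.528). Markers of leukocytes, fibroblasts and endothelium were higher in 2 of 17 cases (4), with a median of 0.12 and adjusted p = 0.066 by fry and 0.0771 by camera. Silent gene families were on average 0.21 higher with nicotine, and 55 of their 505 genes were called. With their array mean as a covariate 24 genes were called, 23 of them among the 3280. Without cisplatin 24 h replicate 3 the count was 38, without cisplatin 24 h replicate 2 it was 6068, and it was 753, 878 and 1697 without cisplatin + nicotine 24 h replicates 1, 2 and 3 and 1653 without cisplatin 24 h replicate 1. It was 1993 with quantile normalization and 5777 without the far arrays. It was 1277 with only the compared groups, of which 356 were higher, and among the genes above the median expression 1871, of which 323 were higher, where 1519 of the 3280 were. Limma's test of whether the nicotine effect differed by therapy called 0 genes at 2 h, with 125 at an unadjusted p under 0.05, and 0 at 24 h, with 2483. The smallest p-values were those of PAGE2B, MRPL34 and SNORA70F at 2 h (adjusted p = 1 each) and of UHRF1, LOC442132 and ZNF814 at 24 h (adjusted p = 0.0652, 0.143 and 0.26), whose log2 interactions with radiation were 1.01, -0.02 and 0.63, and 0.41, -0.55 and 0.62. At 24 h it called 6 genes without nicotine 24 h replicate 2, 2 without cisplatin 24 h replicate 1, and 1 without nicotine 24 h replicate 1, nicotine 24 h replicate 3, radiation 24 h replicate 3 or cisplatin + nicotine 24 h replicate 2. UHRF1 passed in all 6 of these fits (adjusted p from 0.00589 to 0.049), LOC442132 without nicotine 24 h replicate 2 or cisplatin 24 h replicate 1 (adjusted p = 0.0484 and 0.0151) and ZNF814 without nicotine 24 h replicate 2 (adjusted p = 0.0306). Without the 4 far arrays 587 genes were called, and all 3 of these passed (adjusted p = 0.00993, 0.0159 and 0.00156), and UHRF1 did among genes above the median expression (adjusted p = 0.0379).

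**Figure D4:**
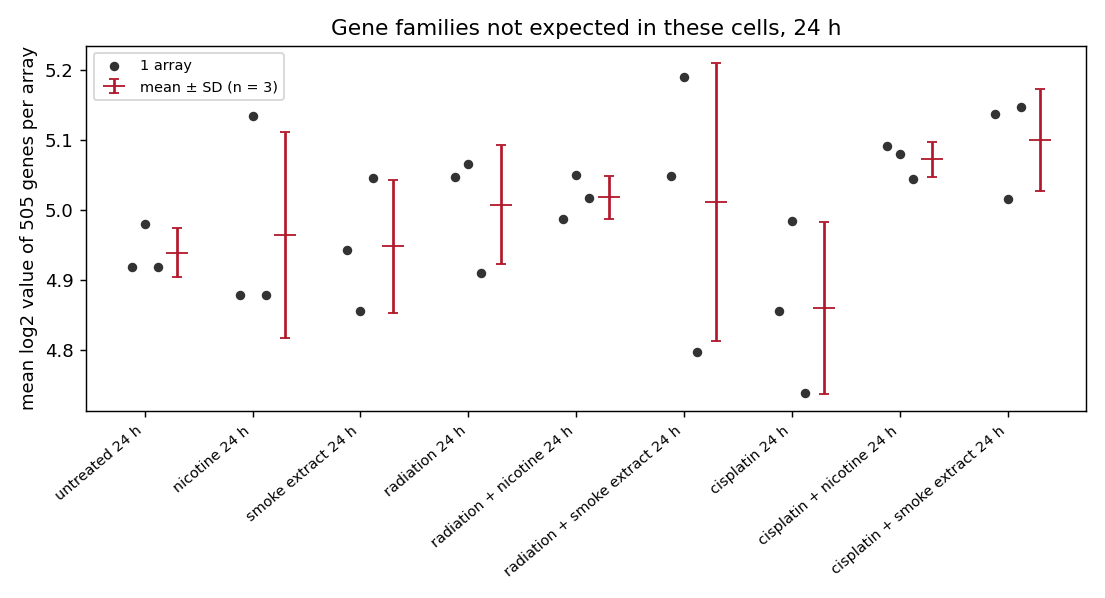
Mean log2 value of 505 genes from families not expected in these cells (vertical axis) on each array of the 9 groups harvested at 24 h (horizontal axis), with 1 point per array and the mean ± SD of 3 arrays beside them. The cisplatin arrays spread from 4.74 to 4.98, below the cisplatin + nicotine arrays at 5.04 to 5.09.

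Time in culture was examined in untreated cells, where 354 genes differed between 24 h and 2 h, 163 higher and 191 lower. CCN1, a matricellular growth regulator, rose 2.05-fold and CXCL8 rose 1.89-fold, while the retinoic acid receptor gene RARB fell by 0.92 ± 0.11 and TDO2 by 0.79 ± 0.15. With quantile normalization 60.1% of the called genes were higher, against 46.0% as deposited. The count was 2681 with only these 6 arrays in the fit, 596 with the silent-family covariate and 694 without the far arrays, and it was 179, 157 and 159 without untreated 2 h replicates 1, 2 and 3 and 146 and 175 without untreated 24 h replicates 2 and 3. With the covariate 380 genes were higher and 216 lower. Markers of leukocytes, fibroblasts and endothelium, cell types that a pure line should lack, were called higher at 24 h in 1 of 17 cases after radiation, 1 after smoke extract, 3 with smoke extract added to cisplatin and 2 with nicotine added to cisplatin, and in 0 cases in the other comparisons of single or added agents. None was called lower. Interferon response genes were called in 3 of 23 cases after radiation, 1 higher and 2 lower, and in 4 after smoke extract, all lower. Genes of the BCL2 family were called in 5 of 15 cases after radiation, 3 higher and 2 lower, and hypoxia and glycolysis genes in 11 of 23, 2 higher and 9 lower, with adjusted p = 0.412 for the latter list with an estimated correlation. Its median was -0.18, and its call also ended with quantile normalization (-0.15, adjusted p = 0.0938), with the covariate (-0.165, adjusted p = 0.0708) and among genes above the median expression (-0.18, adjusted p = 0.15).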

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

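The tests with the silent-family mean, the comparison with ribosomal protein genes and the permutation of residuals were chosen only after the results they bear on were seen. The verdict on that mean in cisplatin-treated cells and its test for mitosis genes were also revised after their first values were seen.

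Several effects differed between groups by a test of the difference itself. The effect of smoke extract differed by therapy in 399 genes at 24 h. The 5 smallest p were those of mitotic genes, with log2 radiation interactions of -1.45 (KIF20A), -1.13 (TOP2A), -1.10 (TPX2), -1.02 (PLK1) and -1.16 (NCAPG). The radiation effect at 24 h differed from that at 2 h in 2396 genes, 1117 with a more positive effect at 24 h and 1279 with a more negative one. The largest positive differences were 1.87 for SULF2, 1.52 for ACTA2, 1.48 for DSC3, 1.45 for MYPN and 1.40 for AADAC. The largest negative ones were -3.05 for VTRNA1-1, -2.85 for RNU5D-1, -2.59 for H3C12, -2.58 for H2BC14 and -2.30 for H2BC9. RNU5D-1 was not called without radiation 24 h replicate 1 (-2.29, adjusted p = 0.0655).

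The cisplatin effect differed between the times in 26 genes, 15 more positive at 24 h and 11 more negative. Differences of 0.958 for SESN1, 0.767 for DGKA, 0.658 for the translesion polymerase gene POLH, 0.64 for PLXNB2 and 0.628 for CLCN4 stood against -1.88 for SNORA3A, -1.76 for SNORA23, -1.27 for RNU4ATAC, -1.02 for SNORA49 and -0.966 for NOP10. This count was 9, 1 and 16 without untreated 2 h replicates 1, 2 and 3, 9 and 15 without cisplatin 2 h replicates 1 and 3, 8, 8 and 15 without untreated 24 h replicates 1, 2 and 3, and 7 without cisplatin 24 h replicate 2. With the silent-family covariate 29 genes were more positive and 60 more negative, and without the far arrays 255 of 309 were more positive. Without untreated 2 h replicate 2 the call of each of these 10 genes but SNORA3A ended (adjusted p from 0.062 to 0.138). Calls also ended for SNORA23 without cisplatin 2 h replicates 1 or 3 or untreated 24 h replicate 2, RNU4ATAC without untreated or cisplatin 24 h replicate 2, and DGKA without cisplatin 2 h replicate 1 or cisplatin 24 h replicate 2 (adjusted p up to 0.074, 0.0721 and 0.057). PLXNB2 lost its call without untreated 2 h replicate 1, cisplatin 2 h replicate 1, untreated 24 h replicates 1 or 2, or cisplatin 24 h replicate 2 (up to 0.141). SNORA49 and NOP10 lost it on leaving out any other array but cisplatin 2 h replicate 2 and cisplatin 24 h replicates 1 and 3 (up to 0.107 and 0.183), and CLCN4 on leaving out any but cisplatin 24 h replicate 1 (up to 0.158), with quantile normalization (0.0665) or the replicate block (0.0616). Over all rows CLCN4 (0.0555) and NOP10 (0.0521) were not called.

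The smoke extract effect differed between the times in 1159 genes, 857 more positive at 24 h and 302 more negative. MMP1 had a difference of 2.88, SCUBE1 2.20, LIF-AS2 2.00, ANKRD36BP1 1.5 and FMOD 1.12, while DEFB1 had -1.75, SNORA20 -1.69, SCARNA10 -1.42, RNVU1-15 -1.37 and RNU5F-1 -1.35. The count was 741, 580, 600 and 702 without untreated 2 h replicate 1, untreated 2 h replicate 2, untreated 24 h replicate 1 and untreated 24 h replicate 2. It was 487, 668 and 676 without smoke extract 2 h replicate 2, smoke extract 24 h replicate 1 and smoke extract 24 h replicate 3. Quantile normalization gave 782 more positive and 495 more negative, and the silent-family covariate gave 1359 and 778. RNU5F-1 was not called with eBayes without trend (adjusted p = 0.053), over all rows (0.0732) or on leaving out any array but untreated 24 h replicate 3 and smoke extract 24 h replicate 2 (0.0565 to 0.169). Calls ended for SNORA20 (0.0727) and SCARNA10 (0.0566) without smoke extract 24 h replicate 1, RNVU1-15 (0.0837) without smoke extract 24 h replicate 3, and ANKRD36BP1 without untreated (0.0677) or smoke extract (0.0896) 2 h replicate 2.

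Signal also appeared in transcript clusters that the gene comparisons left out. Of 13837 clusters without exactly 1 gene symbol, limma called 5 after radiation and 88 after smoke extract at 2 h, and 1488 after radiation, 434 after cisplatin and 1319 after smoke extract at 24 h.

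Of 100 splits of the arrays, 20 called as many genes as the real 399 for smoke extract by therapy at 24 h (highest other 3353). Over time, 6 reached 2396 for radiation (5796), 13 reached 26 for cisplatin (2047) and 6 reached 1159 for smoke extract (2261). These splits do not exclude chance. They mix the agents' separate effects into the difference, which may be why some called several times the real count. That was not tested. With the additive effects kept, the residuals were permuted 100 times, the real one included. Of these draws 4 reached 399 (highest other 3215), 1 reached 2396 (1336), 2 reached 26 (39) and 1 reached 1159 (77). This argues against chance for 2396 and 1159 and leaves it open for 399 and 26, which other draws passed.

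In cisplatin-treated cells at 24 h, nicotine came with 3280 called genes, while the silent families rose by 0.21 and the changes followed the loadings of the main axis of spread within groups at r = 0.842 across genes, which are not independent replicates. With the silent-family covariate the median change of the called genes in the direction called went from 0.374 to 0.188, 50.2% of its size, with 44.7% to 58.8% on leaving out single arrays. Calls of all but 23 of the 3280 genes ended while the median SE went from 0.115 to 0.0955 and 2235 of all genes had an unadjusted p under 0.05, and single genes differed, SNORA38B going only from 1.01 to 0.94. Uneven array quality may account for part of the pattern, and what remained leaves a nicotine effect open. Of the called genes 61% had the same sign with nicotine in irradiated cells under the covariate, with 49.2% to 74.1% on leaving out arrays, so a shared nicotine response cannot be told apart from none.

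Smoke extract lowered mitosis genes more in irradiated cells at 24 h, with a median radiation interaction of -0.81 over 40 genes. The silent-family mean had an interaction of -0.00536 ± 0.118, so as a covariate it could not move this contrast (-0.817). At the slope of these genes on it within groups, -0.656, its 95% interval gives them an interaction no lower than -0.153, which argues against that axis as the main cause and leaves other differences in quality open. Leaving out each of 12 arrays gave medians from -0.899 to -0.716, which argues against 1 atypical array. A joint biological effect of both agents on cell division and a plate effect stay open, untested.

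Small nucleolar and Cajal body RNAs with mean levels above the median gene, which guide the modification of other RNAs, were lower after cisplatin at 24 h, with 45 of 91 called lower, 1 called higher and a median change of -0.477. They were also lower at 24 h after radiation (62 lower, 1 higher, median -0.636) and with smoke extract (29 lower, 2 higher, median -0.236). Causes were weighed for cisplatin, where with the silent-family covariate the median was -0.544 (upper quartile -0.198). This argues against the covariate's axis and leaves other quality differences open. Ribosomal protein genes, also short, had a median of -0.201 over 60 genes (quartiles -0.336 and -0.0807). It was -0.232 after radiation and -0.173 with smoke extract, so poorer recovery of short RNA stays open. The test on host transcripts, with a median of 0.055, is void because 13 of 30 hosts were measured, under the 80% required. A biological effect of cisplatin, or one shared by the 3 agents each given alone, stays open, untested.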

How the results depend on the processing

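The silent-family covariate and the fit without 4 far arrays were chosen after the data were seen, and all other alternatives were planned. Of 237 named gene values, 233 kept their direction and call under quantile normalization, 235 with eBayes without trend, 230 over all rows of the table, 229 with only the compared groups, 223 with the covariate and 228 without the far arrays. Among 191 that stayed above the median of mean expression 188 did so, and 96 of 97 did for the mean over backgrounds. Of 72 list calls 61 held under quantile normalization, 55 with the covariate, 66 without the far arrays, 47 among genes above the median and 18 with an estimated correlation. No background measure was used here, so values near the level of the silent families (4.74 to 4.98 on the cisplatin arrays at 24 h) cannot be told from background. No count of calls moved by over 1.5 times with eBayes without trend. The cause of the moves was not tested.

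With the replicate block 236 of 237 gene values and all 72 list calls held, and no count moved by over 1.5 times. Smoke extract added to radiation at 24 h gave 1528 genes with the block against 1516, and nicotine at 24 h gave 1. These are the 2 comparisons that met the pairing rule, which a match by chance could also meet. In the other comparisons the samples share only a number, pair correlations ran from -0.728 to 0.674 over all 16, and 17 of 48 samples correlated best with their own number.

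With only the compared groups, and so fewer arrays to estimate the spread, the counts at 2 h were 222 for radiation, 1278 for smoke extract, 2 for nicotine, 762 for smoke extract added to radiation and 465 for smoke extract added to cisplatin. At 24 h they were 241 for cisplatin, 0 for nicotine, 651 and 1957 for smoke extract added to radiation and cisplatin, 0 and 1277 for nicotine added to them, 115 for smoke extract by therapy, 816 for radiation against cisplatin and 504 for smoke extract against nicotine. It was 2681 for untreated cells over time, 47 for cisplatin over time and 2690 for smoke extract over time. The mean over the 3 backgrounds gave 249 for radiation, 2 for cisplatin and 1710 for smoke extract at 2 h, and 5992 for radiation, 5096 for smoke extract and 959 for nicotine at 24 h. Over all rows of the table cisplatin gave 2 at 2 h and 1072 at 24 h.

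Genes above the median of mean expression gave 3024 for smoke extract and 1871 for nicotine added to cisplatin at 24 h, 1 for nicotine by therapy at 24 h, 45 for cisplatin over time, a correlation of both therapies at 24 h of 0.648, and 75 called lists against 116. Quantile normalization gave 1993 for nicotine added to cisplatin and 635 for smoke extract by therapy at 24 h. With disjoint controls the correlation at 2 h was 0.114, and with an estimated correlation 18 lists were called.

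With the silent-family covariate the counts were 135 for radiation and 2 for cisplatin at 2 h, 1248 for cisplatin at 24 h, 1317 for smoke extract added to cisplatin at 24 h, 2 and 24 for nicotine added to radiation and cisplatin at 24 h, 1 and 672 for smoke extract by therapy at 2 h and 24 h, 100 for radiation against cisplatin at 2 h, 596 for untreated cells over time, 89 for cisplatin over time and 2137 for smoke extract over time, and the correlation at 24 h was 0.676. Without cisplatin 2 h replicate 3, cisplatin + smoke extract 2 h replicate 3, nicotine 24 h replicate 2 and radiation + smoke extract 24 h replicate 3 together, they were 92 for radiation at 2 h, 1489 for cisplatin and 0 for nicotine at 24 h, 5777 for nicotine added to cisplatin at 24 h, 5 and 1096 for smoke extract by therapy at 2 h and 24 h, 587 for nicotine by therapy at 24 h, 1119 for smoke extract against nicotine at 24 h, 694 for untreated cells over time and 309 for cisplatin over time. Neither scaling moved the median change of all genes by over 0.1.

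Leaving out each array in turn gave 27 to 148 genes for radiation, 450 to 632 for smoke extract, 0 to 5 for smoke extract by therapy and 25 to 130 for radiation against cisplatin at 2 h. At 24 h it gave 2810 to 4250 for radiation, 225 to 689 for cisplatin, 1903 to 2658 for smoke extract, 0 to 4 for nicotine, 1197 to 1828 and 1450 to 7330 for smoke extract added to radiation and cisplatin, 0 to 34 and 38 to 6068 for nicotine added to them, 198 to 1635 for smoke extract by therapy, 0 to 6 for nicotine by therapy, 1404 to 3525 for radiation against cisplatin and 915 to 3866 for smoke extract against nicotine. Untreated cells over time gave 146 to 242, radiation over time 1700 to 2858, cisplatin over time 1 to 36 and smoke extract over time 487 to 1199. The correlation of both therapies ranged from 0.213 to 0.46 at 2 h and from 0.335 to 0.634 at 24 h. With arrays left out 1613 of 1770 gene values kept their call, 127 lost it, 13 gained it and 17 changed sign, and the remaining pair of a group is assumed to vary like the other groups.

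Gene values that changed sign were all uncalled and near 0. Of list medians, nicotinic receptors after cisplatin at 24 h turned to 0.0286 among genes above the median, oxidative phosphorylation with smoke extract added to cisplatin at 24 h to 0.021 with the covariate, and, with nicotine at 24 h and without the far arrays, DNA repair genes to 0.0493 and markers of other cell types to -0.000607, and these calls ended. CHRNA5 with nicotine at 24 h was 0.0042 with quantile normalization, 0.016 without the far arrays and -0.054 to 0.026 with arrays left out. CHRNA5 with nicotine added to radiation at 2 h was 0.0050 with quantile normalization, 0.018 with the covariate and -0.062 to 0.040 with arrays left out. CHRNA7 was 0.056 with the covariate and -0.082 to 0.037 with arrays left out for nicotine added to radiation at 2 h, -0.031 and -0.019 to 0.11 for nicotine added to cisplatin at 2 h, 0.12 with the covariate for nicotine added to cisplatin at 24 h, and -0.076 to 0.18 with arrays left out for nicotine added to radiation at 24 h. With arrays left out, the radiation interaction at 2 h ran from -0.062 to 0.0090 for MRPL34 and from -0.071 to 0.029 for TRIP6, and NQO1 with smoke extract added to radiation at 2 h ran from -0.012 to 0.044.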

Other observations

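Smoke extract also came with lower expression of cholesterol synthesis genes at 24 h. Of 17 measured, 7 fell and 1 rose with smoke extract alone (8 and 1 when adjusted over the list alone), 7 fell when it was added to radiation (11) and 13 fell when it was added to cisplatin (13). With an estimated correlation these calls were lost (adjusted p = 0.359, 0.203 and 0.125 in that order). In cells given cisplatin the silent families were 0.24 higher with smoke extract, and the changes followed the main axis within groups at r = 0.73 across genes. With the silent-family covariate the medians there were -0.23 against -0.33, and 0.22 against 0.38 for the NF-kB genes that follow. STARD4, which carries cholesterol between membranes, fell by 0.96 ± 0.14 with it in cells given cisplatin, the reductase gene DHCR7 fell by 0.37 ± 0.07 and the synthase gene HMGCS1 fell by 0.36 ± 0.08 in cells given radiation, and ACAT2 fell by 0.46 ± 0.09 in cells given cisplatin. Genes of NF-kB and cytokines rose in 12 of 22 cases and fell in 2 when smoke extract was added to cisplatin (14 and 3), and rose in 4 and fell in 2 when it was added to radiation (5 and 2), calls that were lost too (adjusted p = 0.361 and 0.561 with an estimated correlation). IL1A was 6.05-fold, IL1B 2.57-fold and CXCL2 1.70-fold higher in cells given cisplatin, while TNFAIP3, an inhibitor of NF-kB signalling, fell by 0.93 in cells given cisplatin and by 1.30 in cells given radiation. CXCL2 did not pass without cisplatin + smoke extract 24 h replicate 1, where its log2 change was 0.21 (adjusted p = 0.207). With only the compared groups CXCL2 (adjusted p = 0.121), DHCR7 (adjusted p = 0.111) and HMGCS1 (adjusted p = 0.103) did not pass. Among other members of the fixed lists, the glucose transporter gene SLC2A1 rose 1.59-fold in cells given radiation and 1.37-fold in cells given cisplatin, NDRG1 rose 1.86-fold and 1.72-fold, and the early response gene EGR1 rose 2.23-fold in cells given cisplatin.

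When smoke extract was added to cisplatin, replication genes fell in 26 of 39 cases at 24 h (26 when adjusted over the list alone), and interferon response genes fell in 8 of 23 and rose in 2 (9 and 3). With an estimated correlation, adjusted p was 0.245 and 0.359. With the silent-family covariate the interferon list was no longer called (median -0.06 against -0.25, adjusted p = 0.0806), nor was it among genes above the median of mean expression (-0.26, adjusted p = 0.32). Of metallothionein and zinc export genes at 24 h, MT1G fell by 0.68 and MT2A by 0.65 after radiation, where the exporter SLC30A1 rose 1.55-fold. With smoke extract MT1G fell by 0.62 and MT2A by 0.56, and SLC30A1 rose 1.35-fold. In all, 4 of 9 fell and 1 rose after radiation (7 and 1), and 3 fell and 1 rose with smoke extract (8 and 1). Those calls were lost with an estimated correlation (adjusted p = 0.406 and adjusted p = 0.313), that after radiation also among genes above the median of mean expression (-0.39 against -0.28, adjusted p = 0.191), and metallothionein genes can share probes.

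With smoke extract, 214 genes were higher at both times and 126 lower, where independent lists would share 27.7 each way, and 18 went in opposite directions. At 24 h the 3 arrays of each group did not overlap for 38.73% of all 18417 genes with nicotine added to cisplatin. The share was 34.84% with radiation and 9.05% with nicotine alone (chance 10%). Changes in the first followed the main axis within groups (r = 0.842), so the shares do not rank the agents.

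For comparisons of 3 arrays with 3 there are 10 splits, too few for a share under 0.05, so only the real count and the highest other are given. At 2 h these were 56 and 0 for radiation, 1 and 0 for cisplatin, 695 and 0 for smoke extract, 490 and 0 for smoke extract added to radiation, 1005 and 4 for smoke extract added to cisplatin, and 624 and 0 for smoke extract against nicotine. At 24 h they were 3875 and 0 for radiation, 700 and 0 for cisplatin, 2959 and 0 for smoke extract, 1 and 0 for nicotine, 1516 and 564 for smoke extract added to radiation, 5275 and 974 for smoke extract added to cisplatin, 3280 and 8 for nicotine added to cisplatin, and 2349 and 1148 for smoke extract against nicotine. Untreated cells over time gave 354 and 0. In each of these 1 split, the real one, reached the count. Radiation against cisplatin gave 52 with 58 in another split at 2 h and 2403 with 3831 at 24 h, so 2 of 10 splits reached each count. Nicotine gave 0 and 0 alone at 2 h, 0 and 14 added to radiation at 2 h and 0 and 0 added to cisplatin at 2 h, where all 10 splits reached the count, and 1 and 110 added to radiation at 24 h, where 5 did. For the tests of an effect by therapy that called 0 genes, all 100 splits reached the count, with 823 as the highest other for smoke extract at 2 h, 33 for nicotine at 2 h and 2621 for nicotine at 24 h. Why some splits gave many more calls than the real one was not tested. They may mix treatments or divide groups along the spread between arrays.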
